A study of Mus musculus with 19 samples.

How the data were processed

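Liver RNA of 19 male mice of the transgenic strain 40.6, 10 weeks old, was measured 3 days after exposure to dibenz[a,h]anthracene, a polycyclic aromatic hydrocarbon, at 0, 6.25, 12.5 or 25 mg/kg. The groups held 5, 5, 4 and 5 animals, with 1 array per animal. Each Agilent mouse array carried liver RNA in the red dye (Cy5) and a reference RNA pooled from 11 mouse cell lines in the green dye (Cy3), per the labels. The dyes were never swapped, so a value compares liver with the reference on the same array. RNA was extracted with TRIzol and purified on RNeasy columns, and 200 ng per sample was amplified and labelled, per the labels' protocols.

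The scanner files hold the red and green intensity of each spot and of its local background as median pixel brightness on a linear scale, extracted with Feature Extraction 10.7.3.1, per the file headers. They also hold an intensity that the same software had background subtracted and dye normalised. The deposited table of values holds log2 ratios of liver over reference. No label states how that table was made. Its columns correlated at 0.993 to 0.996 across probes with a loess-normalised log2 ratio computed here from the median signals with no background subtraction. Names of unannotated intervals on the array refer to mouse build mm9, per the file headers.

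Red and green median signals were background corrected with normexp (offset 50) and normalised within each array by loess, with control spots given no weight, in limma 3.58.1 under R 4.3.3. The design had named mean signals, but the files used hold medians, so medians took their place. Spots that the scanner software marked as outliers were set to missing (0.132% of the values kept), and spots of the same probe were averaged. A probe was kept when more than a share of 0.5 of its spots was well above background in the liver channel on at least 4 arrays, the size of the smallest group. This kept 29415 of 55681 probes, and probes with more than 2 missing values were left out of a fit. Symbols came from RefSeq accessions in a table of assembly GRCm38.p6, used for names alone, which named 47.4% of the 55681 probes. Of 33064 probes with a RefSeq accession, 79.9% received a symbol. A gene was represented by its brightest kept probe, giving 13812 genes.

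Group means were fitted with limma's lmFit and eBayes over all 19 arrays. Each dose was compared with control and with the other doses, an F test asked whether any dose differed, and a linear trend was fitted on the dose. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 29415 probes, and a probe passed at an adjusted p under 0.05. A log2 change is given with its standard error (SE). Arrays sat on 3 slides, each scanned on its own, with slide 1 scanned 7 days after the others. Every slide held all 4 groups, so the same fit with slide as a fixed block is given beside the counts and many other results. Differences within each slide are given for some of them. Slide 1 held 2 controls and 1 array of each other dose, slide 2 held 2 arrays of each group, and slide 3 held 1 control. A difference within slide 1 or slide 3 therefore rests on a single animal on at least 1 side.

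The lists numbered 30 and held 742 genes, of which 722 were on the array, 638 were kept and 40 belonged to more than 1 list. They covered targets of the aryl hydrocarbon receptor (AhR), p53, Nrf2, CAR and PXR, and PPAR alpha; DNA repair, cell cycle, circadian clock, unfolded protein response, microRNA processing and miR-34a targets; and lipogenesis, cholesterol synthesis, bile acids and glucose metabolism. Others covered male-biased and female-biased liver genes, acute phase, interferon, and immediate early and heat shock genes. The rest were markers of pericentral and periportal hepatocytes and of macrophages, lymphocytes, stellate, endothelial, cholangiocyte, pancreas, adipose and erythroid cells. Lists were tested with limma's camera (preset correlation 0.01) over 13546 genes with a value on every array, adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry (statmod 1.5.0) were run beside it. Fry asks whether the genes of a list move one way on balance, or, in its mixed form, either way, and compares the list with no other genes. List members were also adjusted over the list alone.

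The groups, tests, lists and other settings were chosen before the data were examined. So was the naming rule. It names the measured AhR targets, of which 1 is not reported here, and up to 10 genes with the largest rise and fall at 25 mg/kg that passed with every treated array on the same side of the control mean. It adds the 4 members of smallest p of each list described, the 5 genes of smallest p at a dose where none passed, and the 5 of smallest p each way for the dose trend.

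The other settings were a 1.5-fold limit, only the arrays of the groups compared, each array left out, the mean of a gene's probes, dose as a rank, a trended robust prior, array weights, and slide as a block or each slide alone. They included median centring, loess followed by Aquantile, the liver channel alone, no background correction, the software's processed signals, the deposited table, no filter, and a filter on both channels on all arrays, which kept 16501 probes. Leaving out slide 1, the block with array weights, and the block with each array left out were added after the data were seen. Other splits of the arrays, at most 100 per result, and permutation tests with 100000 resamples were run as well.

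The pipeline was tested on simulated data for 25 mg/kg against control, with 200 of 28712 probes changed. Without the slide block it recovered 16.4%, 82.1% and 100% of probes changed by 0.5, 1 and 2 on the log2 scale, with 2 false calls. With the block it recovered 58.2%, 97.0% and 100%, with 15 false calls. The simulated arrays took their slide effects and spread per probe from the fit with the block, with independent noise for each probe. The better recovery with the block is therefore partly built in, and correlation between genes was not simulated. The number of arrays limits the precision. The microRNA measurements that the series title refers to were not analysed here.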

Results

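The series asked how mouse liver answers a polycyclic aromatic hydrocarbon 3 days after exposure, at 4 doses including none. Liver RNA of 19 animals was compared with a common reference RNA on 19 arrays (5 at 0, 5 at 6.25, 4 at 12.5 and 5 at 25 mg/kg). Liver signal was well above background at 35.5 to 56.7% of spots per array. The share was 47.0% ± 7.90 in controls (SD, n = 5), 48.3% ± 4.81 at 6.25 mg/kg (n = 5), 39.8% ± 5.01 at 12.5 mg/kg (n = 4) and 47.8% ± 6.42 at 25 mg/kg (n = 5). Reference signal was above background at 55.8 to 75.4% of spots, and at 67.5% or more on slide 1.

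Slide separated the arrays more than dose did. The first principal component held 41.8% of the variance, of which slide explained 98.6% and dose group 2.91%. The second held 12.1%, with 73.7% explained by slide, and the third held 7.42%, with 55.7% explained by dose group. The median correlation between arrays was 0.981 within a group and slide, 0.959 within a group across slides and 0.977 between groups on 1 slide. Values from the fit with slide as a block are therefore given beside the counts of each comparison and beside many, though not all, of the genes and lists.

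**Figure D1:**
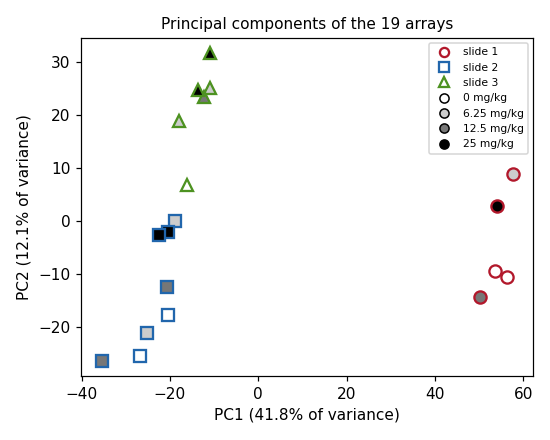
First (x) and second (y) principal components of the 19 arrays, with 41.8% and 12.1% of the variance, 1 point per animal. Symbols mark the slide and shading the dose, and the arrays part by slide along the first component.

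The comparison of 25 mg/kg with control asked what the highest dose changed in liver. The largest rise was on a probe with no symbol (3.91 ± 0.51, adjusted p = 0.0104), and the largest among named genes were in genes of the circadian clock. Dbp, a transcription factor driven directly by the clock, rose 13.1-fold, and Usp2, a deubiquitinase with a daily rhythm in liver, rose 13.9-fold. Nr1d2, a nuclear receptor that represses the clock's positive arm, rose 2.55-fold. Nfil3, a repressor that competes with Dbp for the same sites, fell 2.73-fold. Rises were also seen in Cplane1, a ciliogenesis gene (7.57-fold), Aen, a nuclease induced by p53 (2.03-fold), and Klf13, a zinc finger transcription factor (1.92-fold).

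The log2 change was 3.71 ± 0.54 for Dbp, 3.79 ± 0.58 for Usp2, 2.92 ± 0.43 for Cplane1 and 1.35 ± 0.21 for Nr1d2 (SE, adjusted p = 0.0129 for each). It was -1.45 ± 0.25 for Nfil3 (adjusted p = 0.0396), 0.94 ± 0.16 for Klf13 (adjusted p = 0.0418) and 1.02 ± 0.18 for Aen (adjusted p = 0.0439). By the naming rule, the 5 arrays at 25 mg/kg lay on the same side of the control mean for each of these 7 genes. On slides 1, 2 and 3 the change was 4.21, 2.56 and 4.81 for Dbp, 3.88, 3.17 and 4.06 for Usp2, and -1.27, -1.0 and -1.94 for Nfil3. It was 0.99, 1.08 and 1.16 for Aen and 0.61, 0.81 and 1.21 for Klf13. A further probe of Cplane1 passed with slide as a block alone (1.45, adjusted p = 0.0421; without the block 1.44, adjusted p = 0.177), and another stood at -0.02 (adjusted p = 0.985).

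Across all probes 17 passed at 25 mg/kg, 13 higher and 4 lower, and all 17 changed by at least 1.5-fold. An unadjusted p under 0.05 was reached by 2168 of 29415 probes, where 1471 would be reached by chance. Leaving out 1 array at a time gave between 0 and 67 probes in limma, and between 25 and 320 with slide as a block. The named genes among the 17 probes were 6 higher and 3 lower, and 6 probes had no symbol. Insig2 and Chka passed on a probe other than their brightest and were chosen after their values were seen. Insig2, which holds back cholesterol synthesis, had -2.23 (adjusted p = 0.0188) and, on its brightest probe, -1.70 (adjusted p = 0.055). Chka, a choline kinase, had -1.79 (adjusted p = 0.0439) and -1.46 (adjusted p = 0.0547). An unannotated probe for chromosome 2, 158169020 to 158191295 (mm9), rose by 0.62 ± 0.11 (adjusted p = 0.0418).

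With slide as a block, 238 probes passed, 142 higher and 96 lower, including all 17 with the same sign. The change was 3.83 for Dbp (adjusted p = 0.0026), 3.81 for Usp2 (adjusted p = 0.00878), 1.28 for Nr1d2, -1.40 for Nfil3 and 1.08 for Aen. Further clock genes passed with the block alone. Of these, Arntl, Tef and Wee1 are given although they fall outside the naming rule. Arntl, which encodes the activator BMAL1, fell by 2.47 (adjusted p = 0.0291; without the block -2.33, adjusted p = 0.136). Its changes within the slides were -2.34, -1.53 and -3.28. Tef, a relative of Dbp (1.69 without the block), and Wee1, a cell cycle kinase under clock control (1.91), had adjusted p = 0.0026 and 0.0285 with the block, against 0.0982 and 0.055 without. Por, the electron donor of cytochrome P450 enzymes, had 1.81 (adjusted p = 0.101, with the block 0.0346). The median standard error was 0.146 without the block and 0.105 with it.

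**Figure D2:**
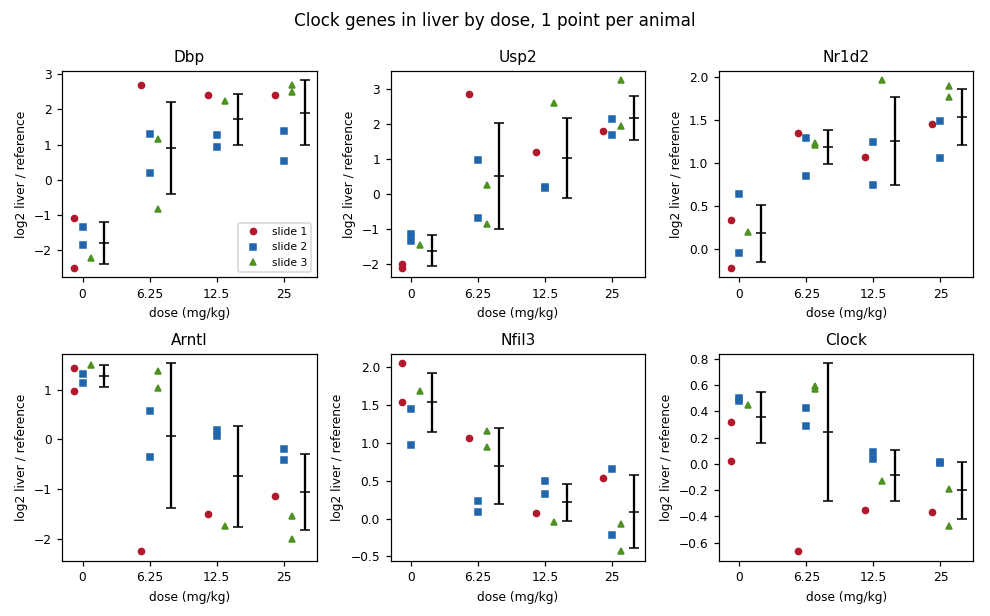
Log2 ratio of liver over reference (y) by dose in mg/kg (x) for 6 clock genes, 1 point per animal with symbols for the slide, and bars for the group mean and SD. Dbp averaged -1.80 in controls and 1.91 at 25 mg/kg.

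The clock list moved as a group at 25 mg/kg. Of 21 measured genes 16 were higher and 5 lower, with a median log2 change of 0.80 and of 1.14, 0.75 and 1.03 on slides 1, 2 and 3. Per1 and Per2, the period genes of the negative arm, had 1.32 (adjusted p = 0.163) and 1.55 (adjusted p = 0.107). Per3 was above background on no control array and was at least 2.10-fold higher. Nr1d1 had 0.07 (adjusted p = 0.983). Per1, Per2, Per3 and Nr1d1 also fall outside the naming rule. Over all probes 3 clock genes rose and 1 fell, and adjusted over the list alone 12 rose and 3 fell. Camera gave adjusted p = 1.07e-07 for the list, and adjusted p = 0.034 with an estimated correlation. With the block these were 3.02e-06 and 0.203.

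Targets of p53, the transcription factor activated by DNA damage, were mostly higher at 25 mg/kg. Aen was the only member that rose over all probes. Ccng1, a cyclin induced by p53, had 1.16 ± 0.30 (adjusted p = 0.204; with the block 0.94, adjusted p = 0.0151). Zmat3, an RNA-binding p53 target, had 0.50 ± 0.13 (adjusted p = 0.204; with the block 0.0164), and Dglucy 0.70 ± 0.16 (adjusted p = 0.134; with the block 0.0369). Cdkn1a, which encodes the cell cycle inhibitor p21, had 1.01 ± 0.41 (adjusted p = 0.558), and Mdm2, the ligase that degrades p53, had 0.23 (adjusted p = 0.616); both were chosen after their values were seen. Of 30 targets 25 were higher, with a median of 0.25 and of 0.16, 0.14 and 0.34 on slides 1, 2 and 3. Adjusted over the list alone 6 rose. Camera gave adjusted p = 4.37e-07 for the list (1.86e-06 with the block), and adjusted p = 0.0542 with an estimated correlation. The DNA repair list had adjusted p = 0.261, with Gadd45a at 0.93, Rev1 at 0.58, Ercc6 at 0.40 and Rad52 at 0.43, and no member passed, over all probes or over the list alone. With the block the list had adjusted p = 0.479, but 4 members rose and 2 fell adjusted over the list alone, and mixed fry gave adjusted p = 1.91e-07 (0.145 without the block).

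**Figure D3:**
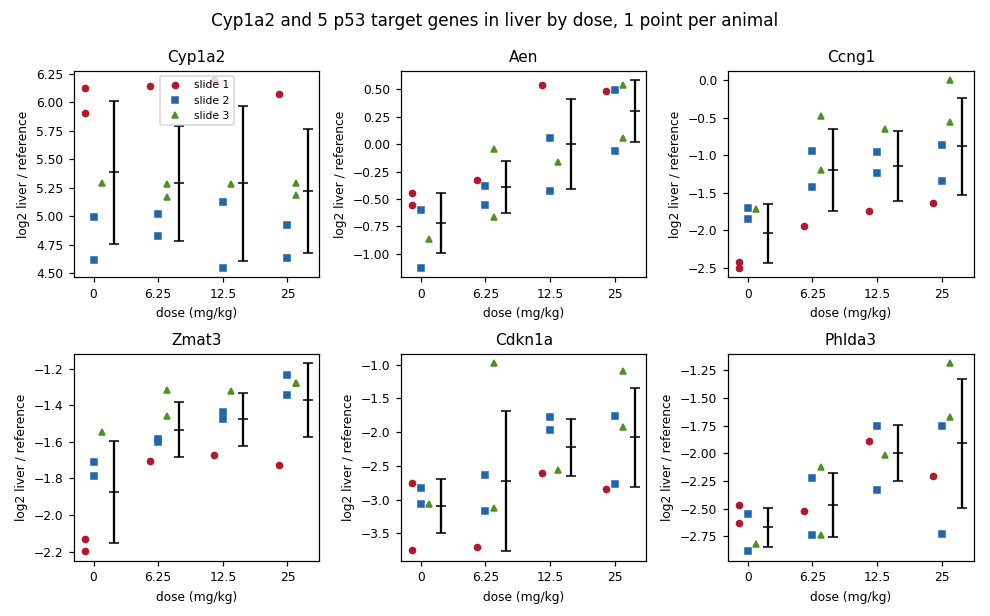
Log2 ratio of liver over reference (y) by dose in mg/kg (x) for Cyp1a2 and 5 p53 targets, 1 point per animal with symbols for the slide, and bars for the group mean and SD. Cyp1a2 averaged 5.39 in controls and 5.22 at 25 mg/kg.

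Cytochrome P450 genes of the AhR, the receptor for this class of compound, did not pass at any dose. Cyp1a1 was above background on 1 of 19 arrays, at 12.5 mg/kg, so no change was measured for it. Cyp1a2 was above background on all 19, with means of 5.39 ± 0.63, 5.29 ± 0.51, 5.29 ± 0.68 and 5.22 ± 0.54 at 0, 6.25, 12.5 and 25 mg/kg (SD). Its change was -0.17 ± 0.34 at 25 mg/kg (adjusted p = 0.938), -0.10 at 12.5 and -0.10 at 6.25 mg/kg. On slides 1, 2 and 3 it was 0.06, -0.03 and -0.06 at 25 mg/kg. Cyp1b1 was above background on 8 arrays, 2 of them controls, and had 0.01 ± 0.28 (adjusted p = 0.996). The AhR repressor Ahrr was above background on at most 1 array per probe, and Adh7 on 3.

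Among the 20 measured AhR targets none passed in limma at 25 mg/kg over all probes, and 3 rose adjusted over the list alone. Among them were Fmo2, a flavin monooxygenase, with 1.10 ± 0.29 (adjusted p = 0.202; with the block 1.25, adjusted p = 0.0151), and the AhR partner Arnt, with 0.48 ± 0.15 (adjusted p = 0.334). Another Arnt probe stood at -0.03. Tiparp had 0.41, Nfe2l2 0.54, Xdh 0.37, Nqo1 0.26, Ugt1a6b 0.18, Tgfa 0.11 and Ugt1a6a 0.10. Gsta1 had -0.52, Ahr -0.21, Htatip2 -0.17, Ugdh -0.12, Gadd45b -0.09, Aldh3a1 -0.08, Cdkn1b -0.06 and Cyp2s1 -0.06. Camera gave adjusted p = 0.099 at 25, 0.191 at 12.5 and 0.0668 at 6.25 mg/kg. With the block the value at 6.25 mg/kg was 0.0485, and 0.521 with an estimated correlation. Fry gave adjusted p = 0.0507 for the list moving one way at 25 mg/kg, and 0.00573 for its genes changing in either direction (with the block 0.0712 and 2.67e-05).

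Genes of protein folding and of cholesterol synthesis were lower at 25 mg/kg as lists. Ddit3, the stress factor CHOP, had -0.96 (adjusted p = 0.0943; with the block 0.0369), the asparagine synthetase Asns -1.12, the chaperone Hsp90b1 -0.70 and Sdf2l1 -0.95. Of 25 unfolded protein response genes 22 were lower, and 4 fell adjusted over the list alone. Their median was -0.49, but slide 1 stood at 0.11 and slides 2 and 3 at -0.34 and -1.23. The value of slide 3 rests on 1 control, whose mean over the list was 1.27, against 0.33 to 0.90 in the other controls. Camera gave adjusted p = 1.82e-06, and adjusted p = 0.301 with an estimated correlation. For cholesterol synthesis 20 of 25 genes were lower (adjusted p = 0.00105, and 0.824 with an estimated correlation), with Sc5d at -0.42, Hmgcs1 at -0.75, Fdps at -0.37 and Mvd at -0.83. The median was -0.25, and -0.47, 0.12 and -0.21 on slides 1, 2 and 3.

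Liver genes with a sex difference went opposite ways as lists. Of 25 male-biased genes 23 were lower, with the fatty acid elongase Elovl3 at -1.49 (adjusted p = 0.268), Gstp1 at -0.72, Cyp2u1 at -0.40 and Moxd1 at -1.68. Of 18 female-biased genes 14 were higher, with the transporter Slc16a5 at 1.62 (adjusted p = 0.0534; with the block 0.0127), Fmo2 as above and Acot3 at 0.86. Another Slc16a5 probe stood at 0.13. Camera gave adjusted p = 0.000161 and 0.000205 for these lists, and 0.86 and 0.118 with an estimated correlation. With the block they were 0.00738 and 0.000778. The male-biased median was -0.32, but -0.17 with the block and -0.12, -0.13 and -0.15 on slides 1, 2 and 3. The female-biased median was 0.31, and -0.04, 0.25 and 0.58 on the slides, so slide 1 showed no rise. Fry, run beside camera, passed the clock list (adjusted p = 0.00215) and the p53 list (adjusted p = 0.0134) and no other list at 25 mg/kg in its one-way form. With the block, female-biased genes passed as well (adjusted p = 0.0473). In its mixed form fry passed 4 lists, the clock (6.96e-06), p53 targets (0.00128), female-biased genes (0.00128) and AhR targets, and 11 with the block.

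The other lists did not pass camera at 25 mg/kg without the block. Pfkfb3, a regulator of glycolysis, had 1.74 and Igfbp1 -2.05 in the glucose list (adjusted p = 0.728), with Foxo1 at 0.38 and Ldha at -0.47. The CAR and PXR list had adjusted p = 0.606, with Por and Abcb1a (0.48), Alas1 (1.13) and Cyp2c55 (-0.36). Its median was -0.07 while its test leaned upward. The PPAR alpha list had adjusted p = 0.258, with Plin2 at -0.69, Fgf21 at -0.84, Pdk4 at -1.28 and Vnn1 at -0.66, and these 4 fell adjusted over the list alone. Cell cycle genes had adjusted p = 0.099 (with the block, lower, 0.00956, and 0.778 with an estimated correlation), with Ccnb1 at -0.55, Tk1 at 0.52, Aurka at -0.27 and Cenpa at -0.39. Adjusted p was 0.317 for Nrf2 targets, 0.298 for lipogenesis and 0.708 for bile acid genes. With the block, mixed fry passed the glucose (adjusted p = 0.00015), PPAR alpha (0.000684), cell cycle (0.00164) and Nrf2 lists (0.0166), and none of these without the block. In the glucose list 4 members rose and 2 fell with the block, adjusted over the list alone.

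MicroRNA processing genes, in view of the series' interest in microRNAs, did not pass at any dose. Dicer1, which cuts precursors into mature microRNAs, had 0.27 at 25 mg/kg (adjusted p = 0.725), Ran -0.32, Ddx5 0.21 and Tarbp2 0.12. Further Ddx5 probes stood at 0.26 and -0.22, the latter at 0.22 with the block. The list had adjusted p = 0.455 at 25, 0.739 at 12.5 and 0.796 at 6.25 mg/kg. Targets of miR-34a, a microRNA under p53 control, had adjusted p = 0.606 at 25 mg/kg, with Dll1 at 0.22, Ccnd1 at 0.39, Map2k1 at -0.17 and Mycn at 0.44. At 12.5 mg/kg the miR-34a list was higher (17 of 20 genes, median 0.12, adjusted p = 0.0246), with adjusted p = 0.473 with an estimated correlation and 0.0711 with the block.

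At 12.5 mg/kg the question was whether a middle dose changed the same genes. Dbp had 3.52 ± 0.57 (adjusted p = 0.0661), Nfil3 -1.33 ± 0.26 and Nr1d2 1.07 ± 0.22 (adjusted p = 0.292 for each). Cplane1 had 2.44 ± 0.46 (adjusted p = 0.239), and Avpr1a, the vasopressin receptor of pericentral hepatocytes, -1.30 ± 0.26 (adjusted p = 0.292). These 5 genes of smallest p did not pass, and limma called 0 of 29415 probes, with 1239 at an unadjusted p under 0.05. With slide as a block 2 probes passed, both of Dbp (3.65 ± 0.51, adjusted p = 0.0257), which had 4.21, 2.70 and 4.45 on slides 1, 2 and 3. Usp2 had 2.66, Aen 0.72 and Klf13 0.69.

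As lists at 12.5 mg/kg, cell cycle genes were higher (28 of 32, median 0.23, adjusted p = 5.82e-08) and p53 targets were higher (24 of 30, median 0.26, adjusted p = 2.52e-07). With an estimated correlation adjusted p was 0.473 and 0.0959. With the block it was 1.03e-07 for each list, without that estimate. Liver signal was dimmest in this group, and whether dim signal accounts for the p53 rise at this dose was not tested. Clock genes were higher on balance (median 0.60, adjusted p = 0.000406, and 0.227 with an estimated correlation), and 7 rose and 2 fell adjusted over the list alone. Acute phase genes (adjusted p = 0.0172) and DNA repair genes (0.0136) were higher. Cholesterol synthesis (5.67e-06), PPAR alpha (0.00155), unfolded protein response (0.00463), male-biased (0.0136) and pericentral genes (0.0203) were lower. With an estimated correlation these had adjusted p = 0.736, 0.473, 0.473, 0.506, 0.59, 0.736 and 0.662 in that order. With the block DNA repair (0.0711), male-biased (0.167) and pericentral genes (0.184) did not pass. With each array left out, camera passed acute phase genes in 14 of 19 fits (adjusted p = 0.682 without 12.5 mg/kg replicate 1). It passed male-biased genes in 16 of 19 (0.723 without 12.5 mg/kg replicate 3). Acute phase medians on slides 1, 2 and 3 were 0.10, 0.03 and 0.75.

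At 6.25 mg/kg, the lowest dose, no gene passed. The 5 of smallest p were Spsb1, a ubiquitin ligase adaptor (-1.02 ± 0.18, adjusted p = 0.275), Mrgpre (-0.89 ± 0.17, 0.354), the olfactory receptor Olfr608 (-0.68 ± 0.13, 0.374), Dbp (2.71 ± 0.54, 0.374) and Nr1d2 (1.0, 0.416). Limma called 0 probes, with 1639 at an unadjusted p under 0.05, and called 0 with the block, where 3447 reached it. Usp2 had 2.13, Nfil3 -0.85, Cplane1 1.25, Aen 0.33 and Klf13 0.56.

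The clock list was higher on balance at 6.25 mg/kg (median 0.48, adjusted p = 5.14e-06, and 0.0868 with an estimated correlation), and 7 members rose and 1 fell adjusted over the list alone. Unfolded protein response (adjusted p = 3.79e-05), male-biased (0.0035), cholesterol synthesis (0.00647) and Nrf2 genes (0.0383) were lower. Female-biased genes (0.00831) and p53 targets (0.00862, median 0.14) were higher. With an estimated correlation these 6 lists had adjusted p = 0.444, 0.963, 0.784, 0.48, 0.43 and 0.444 in that order. With the block the Nrf2 list had adjusted p = 0.104, endothelial markers passed as higher at 0.0073 (0.635 with an estimated correlation) and cell cycle genes as lower at 0.0188 (0.699 with an estimated correlation). Fry passed the clock list alone at this dose (adjusted p = 0.0349).

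Differences between the doses were tested directly. Limma called 0 probes for 25 against 12.5 mg/kg (1171 at an unadjusted p under 0.05), for 12.5 against 6.25 mg/kg (1296) and for 25 against 6.25 mg/kg (632). With the block these were 0, 1 and 0 probes, the 1 having no symbol and a change of -0.82. Cell cycle genes were lower at 25 than at 12.5 mg/kg (adjusted p = 1.38e-15, and 0.246 with an estimated correlation). They were higher at 12.5 than at 6.25 mg/kg (adjusted p = 3.97e-14, and 0.346 with an estimated correlation). Fry gave adjusted p = 0.219 and 0.482 for these, and 0.00567 and 0.0140 with the block, where camera with an estimated correlation gave 0.0901 and 0.12. In all 9 lists passed for 25 against 12.5 mg/kg, 4 for 12.5 against 6.25 mg/kg and 2 for 25 against 6.25 mg/kg, and none of them with an estimated correlation. With the block 7, 6 and 2 lists passed. Besides cell cycle genes, female-biased (adjusted p = 0.00139), CAR and PXR (0.00513), clock (0.00688) and lipogenesis genes (0.0135) were higher at 25 than at 12.5 mg/kg. Macrophage and neutrophil (0.00267), acute phase (0.00996), unfolded protein response (0.0354) and stellate genes (0.0477) were lower. With an estimated correlation these had adjusted p = 0.246, 0.654, 0.431, 0.654, 0.636, 0.765, 0.686 and 0.686 in that order. Targets of p53 (0.0392) were higher, and PPAR alpha (0.0367) and pericentral genes (0.0243) lower, at 12.5 than at 6.25 mg/kg, each with adjusted p = 0.805 with an estimated correlation. Lipogenesis genes (2.54e-05) and p53 targets (0.000276) were higher at 25 than at 6.25 mg/kg, with adjusted p = 0.765 and 0.535 with an estimated correlation.

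The trend over dose, fitted with the controls included, asked which genes followed the dose. A step between control and treated animals also gives a slope. Passing the trend therefore does not show that a gene followed the dose among treated animals. Cplane1 rose by 2.84 ± 0.45 from 0 to 25 mg/kg (adjusted p = 0.0335), the top probe without a symbol by 3.70 ± 0.51 (adjusted p = 0.0117), Aen by 1.02 ± 0.17 (adjusted p = 0.0487) and Usp2 by 3.47 ± 0.60 (adjusted p = 0.0496). Trib1 (0.68, adjusted p = 0.0908) and Pcsk4 (1.30, adjusted p = 0.0937) did not pass. Among falling genes Nfil3 had -1.35, Insig2 -1.57 and Atf5, a stress-response factor, -0.95 (adjusted p = 0.099 for each), and Spon2 had -1.45 and Adprh -0.45 (adjusted p = 0.115 for each). The further Insig2 probe passed with -2.05 ± 0.35 (adjusted p = 0.0496). In all 6 probes passed the trend, 5 rising and 1 falling, and 71 with slide as a block, 52 rising and 19 falling. The F test over all doses called 3 probes, both of Dbp and 1 without a symbol (adjusted p = 0.0496), and 22 with the block.

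Changes at the 3 doses were compared with each other over 28712 probes, all against the same controls. The correlation across probes was 0.647 for 25 with 12.5 mg/kg, 0.770 for 25 with 6.25 mg/kg and 0.577 for 12.5 with 6.25 mg/kg. Unchanged groups and a shared control were simulated by shuffling the residuals of all arrays, their distances from the group means, over all groups. The correlation then averaged 0.434, 0.488 and 0.417 over 100 draws, with draws as high as 0.863, 0.950 and 0.849. Unlike the real groups, the simulated ones need not hold arrays of every slide, so slide differences may enter the simulated values. The covariance was 0.0295, 0.0346 and 0.0230, against simulated 0.0193, 0.0219 and 0.0184. With the controls split between the doses the mean correlation over 20 splits was 0.169, 0.247 and 0.0764. Single splits ran from -0.198 to 0.485, from -0.126 to 0.497 and from -0.290 to 0.355, so they do not settle whether the doses share a response. Slide 3 held 1 control, so the parts of the controls always differed in slide, which may enter these values too. At an unadjusted p under 0.05, 201, 356 and 133 probes were higher at both doses, where independent lists give 17.8, 32.8 and 13.4. Probes lower at both numbered 335, 376 and 198, against 26.1, 26.4 and 19.6. Probes are not independent replicates, and part of the excess may come from the shared controls.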

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

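The counts of splits for probes and for numbers of lists were planned. The splits for single lists, the refits of the highest splits with slide, and the tests of slide, phase, dose, dim signal, clock score and single arrays were chosen only after the results were seen.

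Clock genes were shifted at every dose. Within slides, only at 25 mg/kg did no other split give the list as small an adjusted p, which does not exclude chance. The clock score, the mean of the genes signed by their phase, was higher by 1.51 ± 0.25, 1.17 ± 0.27 and 0.95 ± 0.25 at 25, 12.5 and 6.25 mg/kg. A difference between slides as the whole cause is argued against, since 102% of the change at 25 mg/kg stayed with slide as a block, and slides 1, 2 and 3 gave 1.57, 1.08 and 1.92. All 15 genes assigned a phase moved toward their late-day level at 25 mg/kg, 15 at 12.5 and 14 at 6.25 mg/kg, which is consistent with controls collected at another clock phase than treated animals. A direct effect of the compound that grows with dose cannot be told apart from it: the slope over the 14 treated arrays had permutation p = 0.0503, and the labels give no hour of collection. A clock shift caused by the compound also stays open, untested. The counts of genes at the 3 doses are not independent, since the doses share their controls and the genes belong to the same clock. They cover the 15 genes assigned a phase, fewer than the 21 measured in the clock list. Only the direction of a change was counted, whatever its size, and the clock score was built from the same 15 genes. The counts alone therefore cannot decide the phase at collection.

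Targets of p53 were higher at 25 mg/kg, by 0.32 ± 0.08 as a list mean. Slide as the whole cause is argued against by the 91.0% of this that stayed with the block. Dim liver signal is argued against by a change of 0.295 ± 0.0744 beyond genes matched on both channels. The change was 0.498 ± 0.146 with the clock score and slide in the fit, but this cannot decide whether the clock shift is the cause. The clock score ran from -0.294 to 0.192 in controls and from 1.16 to 2.04 at 25 mg/kg, so it could not be held apart from dose. Chance stays open, since 4 of 54 splits within slides gave the list an adjusted p as small, and so does a response to DNA damage by the compound, as a hypothesis found and tested on the same arrays.

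Cell cycle genes were higher at 12.5 mg/kg, by 0.22 as a list mean, in the group with the dimmest liver signal. Dim signal cannot be told apart from a real change, since the list exceeded genes matched on both channels by 0.0726 ± 0.0579 with slide as a block. Without the block the excess was 0.0865 ± 0.0615 and the matched genes were themselves higher by 0.136. Slide as the whole cause is argued against by the 82.6% that stayed with the block (0.18 ± 0.06), and a single array by the lowest value of that fit with 1 array of either group left out, 0.148 ± 0.0555 (without control replicate 5). An effect of this dose stays open: the list differed from 25 and from 6.25 mg/kg in camera (1.38e-15 and 3.97e-14, but 0.246 and 0.346 with an estimated correlation), and dim signal in this group enters those comparisons too.

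The arrays were also split in other ways into groups of the same sizes, with 100 splits that include the real one. For 25 mg/kg against control 2 of the 100 splits, the real one included, gave as many as the real 17 probes (highest other 40). This makes chance less likely but does not exclude it. For the F test 4 gave as many as the real 3 (highest other 1190), and for the trend 3 as many as the real 6 (highest other 1852), again with the real one. Splits that call many times the real count point to a structure of the samples, and for the largest of them that structure is slide: refitted with slide as a block, the splits with 40, 1190 and 1852 probes, and those with 1270 at 12.5 and 50 at 6.25 mg/kg, each gave 0. The splits with 40, 1270 and 50 put 3 slide 1 arrays in the dosed group and 0 in control, that with 1852 put 0 at 25 mg/kg and 2 in control, and that with 1190 put 0 and 1 there. The highest splits for 12.5 against 6.25 mg/kg (7 probes) and 25 against 6.25 mg/kg (6 probes) gave 14 and 16 with the block, so slide does not account for those. Within slides, only the real split reached the real 238 probes at 25 mg/kg (1 of 54, highest other 80) and the real 71 of the trend (1 of 100, highest other 5).

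Where 0 probes passed, all 100 splits gave at least as many by construction, so the splits say nothing about chance there. The highest others were 1270 for 12.5 and 50 for 6.25 mg/kg against control, 1 for 25 against 12.5, 7 for 12.5 against 6.25 and 6 for 25 against 6.25 mg/kg. For the number of lists chance could not be excluded: with the real split counted, 73 splits reached the real 6 lists at 25 mg/kg (highest other 16), 39 the real 11 at 12.5 (highest other 19) and 65 the real 7 at 6.25 mg/kg (highest other 18).

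For single lists the splits with an adjusted p as small are counted with the real one, of 100 splits across slides and then within slides with slide as a block. Clock genes at 25 mg/kg gave 1 (1.07e-07, smallest other 1.44e-05) and 1 of 54 (3.02e-06, smallest other 0.000352), which makes chance less likely in both. It does not exclude chance, since the list was picked from 30 after the results were seen. The clock at 12.5 mg/kg gave 2 (0.000406, smallest other 6.91e-05) but 2 of 36 within slides (0.00218, smallest other 0.000805). At 6.25 mg/kg they gave 4 (5.14e-06, smallest other 2.96e-09) but 5 of 54 within slides (9.68e-05, smallest other 8.74e-08). Within slides chance could therefore not be excluded for the clock list at the lower doses.

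Targets of p53 at 25 mg/kg gave 2 splits (4.37e-07, smallest other 6.73e-08) but 4 of 54 within slides (1.86e-06, smallest other 1.08e-07), where chance could not be excluded. At 12.5 mg/kg they gave 1 (2.52e-07, smallest other 5.25e-07) and 1 of 36 within slides (1.03e-07, smallest other 1.28e-07), and at 6.25 mg/kg 7 (0.00862, smallest other 0.000403) and 14 of 54 (0.0157, smallest other 9.47e-06). Dim liver signal at 12.5 mg/kg was not tested for the p53 list. Female-biased genes at 25 mg/kg gave 1 (0.000205, smallest other 0.00026) and 1 of 54 (0.000778, smallest other 0.00138). Across slides chance could not be excluded for unfolded protein response genes (12 splits, 1.82e-06, smallest other 7.87e-13), cholesterol synthesis (23 splits, 0.00105, smallest other 1.53e-12) or male-biased genes (24 splits, 0.000161, smallest other 1.22e-11) at 25 mg/kg, and these were not split within slides.

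Single animals far from the rest of their group appeared in 13 of 164 groups of values, where chance gives about 1 in 20 groups. At 6.25 mg/kg, replicate 5 had Insig2 at 0.60 (others 2.45 to 2.92), Atf5 at 1.16 (1.68 to 1.81) and Ugt1a6b at 4.15 (3.56 to 3.66), and 75.4% of its reference spots above background (62.2 to 63.8). Replicate 1 had Cplane1 at 0.76 (-1.15 to -0.84) and Gadd45b at -3.34 (-3.51 to -3.47), and replicate 4 had Cyp2s1 at -2.05 (-2.92 to -2.68) and Nr1d2 at 0.85 (1.21 to 1.35). At 12.5 mg/kg, replicate 1 had Aldh3a1 at -1.14 (-0.82 to -0.77) and replicate 3 had Trib1 at -0.29 (0.29 to 0.38). At 25 mg/kg, replicate 2 had Insig2 at 2.04 (1.27 to 1.44) and replicate 4 had Gadd45b at -3.79 (-3.50 to -3.40). Control replicate 5 had Xdh at -0.18 (0.57 to 0.85). The reference share of 75.4% is ordinary for its slide, since that animal was the only one of its group on slide 1, whose arrays all had 67.5 to 75.4%. No explanation was tested for the gene values.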

How the results depend on the processing

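Leaving out slide 1, slide as a block with array weights, and the block with each array left out were chosen only after the results were seen. Probes at 25 mg/kg against control numbered 238 with slide as a block, 134 with array weights, 557 with both, 48 with only the groups compared, 33 with a trended robust prior, 29 without slide 1, 27 with the liver channel alone, 10 with no filter and 5 with median centring. At 12.5 mg/kg they numbered 2 with the block, 7 with block and weights, 6 with only the groups compared and 3 with both channels filtered. For 12.5 against 6.25 mg/kg the block gave 1, and 1 with weights; for 25 against 12.5 mg/kg processed signals gave 1 and leaving out slide 1 gave 1. The F test gave 22 with the block, 12 with weights, 101 with both, and 0 with no background correction, processed signals, median centring, the deposited table or no filter. The trend gave 71 with the block, 120 with weights, 261 with both, 40 without slide 1, 27 with dose as a rank, 2 with no filter, 1 with median centring and 0 with processed signals. The cause was not tested, except that fewer arrays or more probes enter by construction.

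Lists numbered 11 at 25 mg/kg with median centring, and 7 at 12.5 mg/kg with the block (7 with weights) and 6 with processed signals or the liver channel alone. With an estimated correlation they numbered 1, 0 and 0 at 25, 12.5 and 6.25 mg/kg, with fry 2, 0 and 1, and with mixed fry 4, 1 and 1 (with the block 11, 7 and 6). Signs reversed for female-biased genes with both channels filtered (adjusted p = 0.940 at 25 and 0.850 at 6.25 mg/kg) and for cholesterol synthesis at 6.25 mg/kg without slide 1 (0.719); the cause was not tested.

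Leaving out each array gave 0 to 67 probes at 25 mg/kg: 0 without 25 mg/kg replicate 1, 1 without control replicate 4, 7 without control replicates 1 or 5 or 25 mg/kg replicate 2, 8 without 25 mg/kg replicate 3, 9 without 6.25 mg/kg replicate 2, 10 without control replicate 2, 6.25 mg/kg replicate 4 or 12.5 mg/kg replicate 4, 28 without 12.5 mg/kg replicate 1, 32 without 6.25 mg/kg replicate 1 or 25 mg/kg replicate 5, and 67 without 6.25 mg/kg replicate 5. The trend ranged from 0 (without 25 mg/kg replicates 2 or 3) to 83 (without 6.25 mg/kg replicate 5) and the F test from 0, in 15 of 19, to 12. At 12.5 mg/kg the range was 0 to 5 (5 without 6.25 mg/kg replicate 1, 4 without 25 mg/kg replicate 4), with 7 (without control replicate 5) to 16 lists (without 12.5 mg/kg replicate 4). With the block the ranges were 25 (without control replicate 1) to 320 at 25 mg/kg, 4 to 263 for the trend, 0 to 102 for the F test, 0 to 15 at 12.5, 0 to 19 at 6.25, 0 to 3 for 12.5 against 6.25, 0 to 5 for 25 against 12.5 and 0 to 1 for 25 against 6.25 mg/kg.

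Dbp passed in 14 of 14 alternatives and Usp2 in 13 of 13, Cplane1 and Nr1d2 in 12 of 14, Aen in 11, Nfil3 in 9 and Klf13 in 7. With each array left out, Dbp and Cplane1 passed in 17 of 19 fits, Usp2 and Nr1d2 in 16, Nfil3 in 10, Klf13 in 7 and Aen in 6; with the block too, Klf13 passed in 15, Nfil3 in 18 and the other 5 in 19. The clock, p53 and unfolded protein response lists passed camera with its preset correlation at 25 mg/kg in all 15 processing settings. With an estimated correlation p53 targets (adjusted p = 0.0542) and unfolded protein response genes (0.301; fry 0.158) did not pass, nor did the clock list with the block (0.203). No paired analysis was possible because the labels give no litter, cage or day that pairs animals, and replicate numbers follow the order of the samples alone. Liver signal above background at 35.5 to 56.7% of spots limits what could be seen of dim genes such as Cyp1a1.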

Other observations

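The tests of relations with the clock score were chosen only after the results were seen. Within groups, with group and slide removed, 4 lists were compared with the clock score over 19 arrays, with permutation p-values adjusted over the 4. Cholesterol synthesis genes had r = -0.477 (permutation p = 0.0389, adjusted p = 0.125, rho = -0.409), and -0.246 without the 2 arrays farthest from the median, so the relation rests on those arrays. Targets of p53 had r = -0.437 (permutation p = 0.0623, adjusted p = 0.125, rho = -0.304; -0.396 without 2). Unfolded protein response genes had r = -0.312 (permutation p = 0.194, adjusted p = 0.247, rho = -0.368; -0.186 without 2), and female-biased genes r = 0.280 (permutation p = 0.247, adjusted p = 0.247, rho = 0.332; 0.116 without 2). For rho the adjusted permutation p was 0.207 for all 4. No relation passed, and whether these lists follow the clock cannot be told apart from chance at this number of arrays.

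Markers of other cells and of the liver's zones did not pass camera at 25 mg/kg. Pericentral genes had adjusted p = 0.336, with Avpr1a at -1.12 (adjusted p = 0.109; with the block 0.0421), Rnf43 at 0.36, Sp5 at 0.56 and Aldh1a1 at -0.27. Periportal genes had 0.606, with Ctsc at 0.48, Cdh1 at -0.38, G6pc at -0.56 and Gls2 at 0.24. Adjusted p was 0.309 for macrophage and neutrophil, 0.317 for lymphocyte, 0.667 for stellate, 0.667 for endothelial, 0.667 for cholangiocyte, 0.298 for pancreas, 0.667 for adipose and gallbladder and 0.261 for erythroid markers. Interferon genes had 0.258, with Isg15 at -0.61 and Irf7 at -0.70, acute phase genes had 0.799, with C3 at 0.33, and immediate early and heat shock genes had 0.728, with Dnajb1 at -0.85 and Hspa1a at -1.02. With the block, mixed fry passed cholangiocyte markers (adjusted p = 0.00101, and 0.504 without the block). Of these markers 2 rose and 2 fell with the block, adjusted over the list alone.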
